A study of Mus musculus with 2 samples.

How the data were processed

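H3K4me1, the monomethylated form of lysine 4 of histone H3, was profiled by ChIP-seq in the liver of mouse embryos at embryonic day 15.5. Per the labels, the animals were of strain B6NCrl, male and female embryos were pooled, and each of the 2 biological replicates was a separate pool, of 78 embryos for replicate 1 and 62 for replicate 2. The series therefore holds 1 group of 2 libraries, and no treatment, age or tissue is contrasted within it. A control library is named in the labels as a possible control and was not analysed here.

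The 4 peak lists used were: 1 list called on each replicate, 1 list called on the reads of both replicates, here named the pooled list, and 1 list that the text deposited with the samples derives from the pooled list and both replicate lists, here named the replicated list. All are narrowPeak lists on genome build mm10, per the labels and the text deposited with the samples. The fold of each peak is a ratio over the control that the authors' caller wrote, and it was used only to describe, rank or filter peaks within a list. The deposited −log10 p and −log10 q of each peak were used in the same way. The lowest −log10 p in any list lay just above 2 (2.01 in the pooled list). The aligner, the peak caller, its fragment length and its threshold are not given in the sources used here. Peak lists hold no read totals, so the depth of each library is unknown, and no interval that needs read counts is given. Peaks with −log10 q from 0.601 upward were kept in the lists, so weak peaks, whose call depends most on depth, are part of each replicate list.

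Peaks on chromosomes 1 to 19 and X were analysed. The lists held 0 peaks on Y and between 5 and 9 on scaffolds. Gene positions were those of GENCODE on GRCm38, the assembly that mm10 names, and 21728 protein-coding gene symbols were used. For each gene, the percentage of bases within 50 kb on either side of the transcription start site (TSS) that merged replicated peaks covered is called window coverage. The TSS is the 5′ end of the whole gene model, so promoters further inside a gene are not centred. The replicated list is a single list for the series and gives no SD. The window coverage from each replicate's own list stands beside some of the examples and shows the spread between the replicates. It is not a spread around the replicated value, which rests on peaks called on the pooled reads and often lay above both.

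The shared portion of 2 lists was the share of peaks covered over at least 50% of their length by the merged peaks of the other list, and the Jaccard index was taken over covered bases. Chance levels came from a permutation test with 100 circular shifts of the list along each chromosome, between its first and last sequenced base, and the smallest p this allows is 0.0099 for a one-sided and 0.0198 for a two-sided test. Interval counts were made with numpy 2.4.6 and cross-checked with bedtools 2.31.1.

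For each of 17 gene lists, the median window coverage was set against 10000 random lists of the same size drawn from all protein-coding genes and matched on decile of the number of protein-coding TSSs in the window, which serves as a permutation of gene labels within deciles. Genes were drawn with replacement, and the random lists were not thinned to 1 gene per locus. The two-sided p was adjusted over the 17 lists by the Benjamini-Hochberg procedure, with a threshold of 0.05. Where windows of members overlapped, 1 member per locus entered the test. Lists held 366 symbols besides the olfactory receptors, of which 1 (Anxa13) was not matched, and 0 stood in more than 1 list. The units of these tests are genes, not animals, so the p-values describe these libraries. Hepatocyte and erythroid lists were compared by a permutation test of the difference in mean coverage with 100000 resamples. Peaks within 12.5 kb of each other were stitched into domains, the 500 domains with most covered bases were kept, and the lists were tested for membership by Fisher's exact test against all protein-coding genes. Random draws used fixed seeds, with python 3.11.15, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

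The gene lists, tests, thresholds and the rule for naming genes were set before the data were examined. The rule named a fixed panel of genes; the 3 members with the highest and the 1 with the lowest coverage of each list past its threshold, and the highest member of each other list; the 10 genes of highest coverage genome-wide, 1 per locus; the 5 peaks of highest fold and the 5 largest domains; and the 5 genes with the largest difference between replicates in each direction, also 1 per locus. Genes named as the place of a peak or as members of a domain come with the peak or domain that the rule names; the strongest peak in a gene's window is given where a named gene is placed. Alternatives were a stricter threshold (−log10 q of at least 5), other overlaps and list lengths, windows of 10 kb, gene bodies, unmatched random lists, all members kept, other stitching, and each replicate's list alone.

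The interval code was tested on simulated data, where 0 queries differed from base-by-base counts and a planted share of 59.0% of shared peaks was recovered as 59.0%. The list test was run on shuffled window values of the 21728 genes. Of 1000 lists of 24 genes with no planted effect, 4.9% fell under the threshold before adjustment. With a planted fold of 2 in window coverage, 49.5% of 200 lists were recovered, and with a fold of 4, 87.0%. A list that misses the threshold can thus still differ from other genes by a fold of 2.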

Results

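Monomethylation of histone H3 at lysine 4 marks enhancers and the flanks of active promoters. It was mapped in the liver of embryonic day 15.5 mice, an organ that at this stage is built by hepatoblasts and is also the main site of blood formation. The data were 4 peak lists from 2 biological replicates, pools of 78 and 62 embryos of mixed sex: 1 list per replicate, the pooled list and the replicated list. Sequencing depth is unknown, since peak lists hold no read totals. With 1 group of 2 libraries, the comparisons the design implies are between the replicates and between groups of genes within these livers.

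The longest H3K4me1 peak, which also had the highest fold in the pooled reads, lay over Zfpm1, which encodes FOG1, the cofactor of the erythroid regulator GATA1. It spanned chromosome 8 from 122284073 to 122332531 on mm10, 48459 bp, with its summit in an intron of Zfpm1 and a fold of 15.4 over control as given by the authors' caller. Overlapping peaks stood in each replicate's own list, with a fold of 10.1 in replicate 1 and 14.6 in replicate 2. The replicated peaks next in fold lay in an intron of Llgl2 (chromosome 11, 115841081 to 115844872, fold 15.3; 13.1 in replicate 1 and 15.05 in replicate 2, above Zfpm1 in each), over a coding exon of Ntn3 (chromosome 17, 24191504 to 24213548, 14.3), in an intron shared by the overlapping models of Samd4b and Pak4 (chromosome 7, 28594230 to 28597898, 14.3), and between genes 2053 bp from the TSS of Midn (chromosome 10, 80144880 to 80148644, 14.2; 11.2 and 15.54, also above Zfpm1 in each).

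The replicated list held 111088 peaks with a median length of 616 bp, which covered 103.1 Mb or 4.03% of the sequenced bases. Replicate 1 had 171177 peaks over 96.4 Mb, with a mean length of 563 bp. Replicate 2 had 179635 peaks over 89.9 Mb, with a mean length of 501 bp. The pooled list was the longest, with 211713 peaks over 129 Mb. Coverage around genes was uneven: the median window coverage of the 21728 protein-coding genes was 6.19%, the upper quartile began at 16.6%, and 4908 genes (22.6%) had no replicated peak within 50 kb of their TSS.

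Whether the same regions carried the mark in both pools was asked by overlap of the replicate lists. Strong peaks were shared almost without exception: in the top decile by −log10 p, 99.4% of replicate 1 peaks and 99.7% of replicate 2 peaks were covered over at least 50% of their length by the other list. In the lowest decile the shares were 25.4% and 30.6%. Over whole lists, 55.5% of replicate 1 peaks and 60.2% of replicate 2 peaks were shared, against 3.70% and 3.98% after shifting (one-sided permutation p = 0.0099 for each, the smallest that 100 shifts allow). The Jaccard index of covered bases was 0.546, against 0.0205 after shifting (one-sided permutation p = 0.0099). Peaks of replicate 1 that were not shared were shorter than shared ones (median 257 against 476 bp) and weaker (median −log10 q of 2.57 against 5.19). Across 103188 pairs of mutually best overlapping peaks, Spearman's rho of the fold was 0.660; peaks are not independent replicates, and no p is given. When peaks were required to overlap over 80% of their length, the shares were 35.0% and 43.9%.

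**Figure D1:**
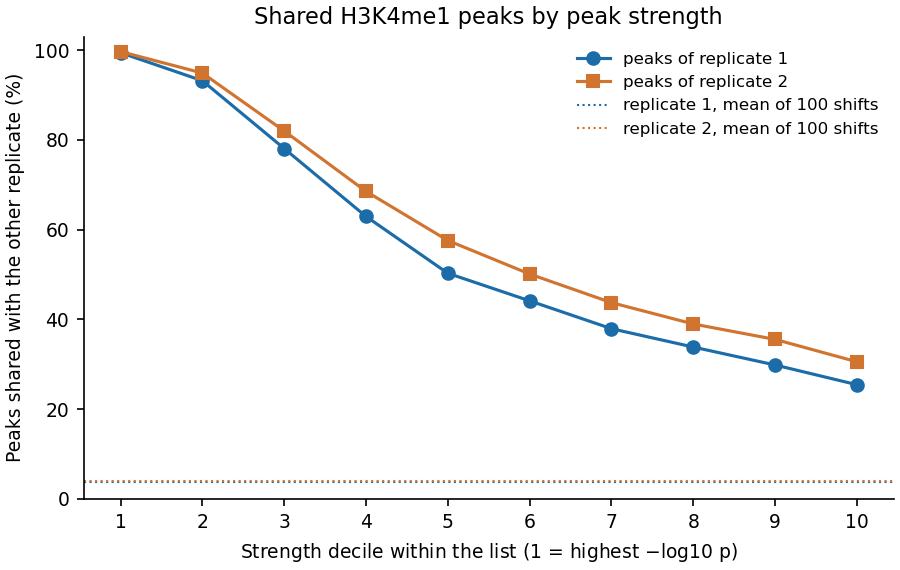
The horizontal axis gives the strength decile of peaks within each replicate's list, with 1 the strongest by −log10 p, and the vertical axis the percentage of peaks covered over at least 50% of their length by the other replicate's list; circles are replicate 1, squares replicate 2, and dotted lines the means of 100 shifted lists. Shares ran from 99.4% and 99.7% in the top decile to 25.4% and 30.6% in the lowest, all above the shifted levels of 3.70% and 3.98%.

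At the level of gene windows the pools were nearly the same. Across all 21728 genes, Spearman's rho of window coverage between the replicate lists was 0.992, and the median difference, replicate 1 minus replicate 2, was 0.270 percentage points. Taking 1 gene per locus, the genes with the largest excess in replicate 1 were Dgat2, a triglyceride synthesis enzyme (38.1% in replicate 1 against 28.4% in replicate 2), Notch1 (29.1% against 19.6%), the histone gene Hist1h3f (43.6% against 34.5%), Tnnc1 (31.4% against 22.7%) and Abca7 (46.8% against 39.2%). The excess in replicate 2, again with 1 gene per locus, was smaller, at most 4.56 percentage points, at Nfya (30.3% in replicate 1 against 34.8% in replicate 2). Cd44, Acot11, Kif3a and Ggta1 followed. These are extremes of 2 libraries and were not tested. Of the 17 gene lists, the median coverage moved most, relative to all genes, for megakaryocyte and platelet genes, at 11.98% in replicate 1 and 15.6% in replicate 2, a relative difference of −4.21 percentage points, which was −1.27 among peaks with −log10 q of at least 5. In both replicates that median is the value of 1 gene, Treml1, and 10 of the 19 loci were higher in replicate 1. Among the stricter peaks the erythroid (1.86) and macrophage (1.54) lists moved more, and by the log2 ratio of means over whole lists, relative to all genes, stellate and mesenchymal genes (0.15) moved more than megakaryocyte genes (−0.07).

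The replicated list was a subset of the pooled list. All 111088 replicated peaks stood in the pooled list with the same position and name, and they made up 52.5% of its peaks. They took in 99.995% of pooled peaks in the strongest decile and 3.81% in the weakest. Of the replicated peaks, 84.1% were covered over at least 50% by replicate 1 peaks and 80.7% by replicate 2 peaks. A rule of overlap over 50% of either peak with a peak of each replicate was met by 96278 pooled peaks, all of which were in the replicated list. The other 14810 replicated peaks (13.3%) did not meet it: 13931 of them touched a peak of 1 replicate only and 361 touched none.

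H3K4me1 was concentrated on promoters and their flanks. Coverage was highest from 500 to 1000 bp from the nearest protein-coding TSS, at 33.1% of bases, and lower next to the TSS itself, at 26.7% within 250 bp. It was 12.6% from 2 to 5 kb and 0.625% beyond 100 kb. Against shifted lists these were enrichments of 7.76, 6.25 and 2.95-fold and a depletion to 0.160 of the shifted level (two-sided permutation p = 0.0198 for each of the 10 distance bins, the smallest that 100 shifts allow). By midpoint, 58.0% of replicated peaks lay in introns, against 42.8% ± 0.781 (SD over 100 shifts). Promoters, within 1 kb of a TSS, held 11.6% of midpoints, against 1.68% ± 0.0677, other exons 8.89%, against 4.70% ± 0.140, and intergenic space 21.6%, against 50.8% ± 0.823.

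**Figure D2:**
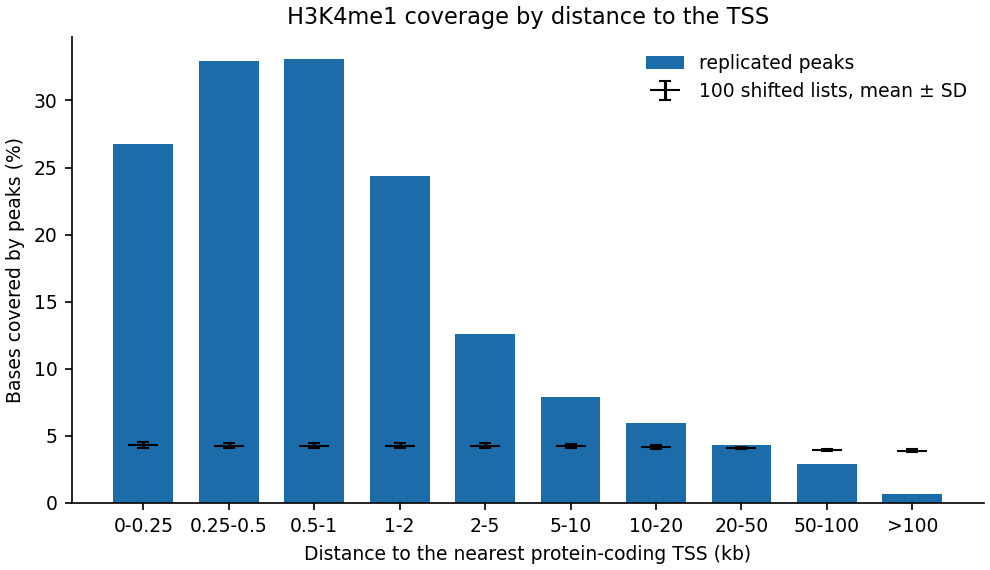
Bars give the percentage of bases covered by replicated peaks (vertical axis) in bins of distance to the nearest protein-coding TSS (horizontal axis, kb); horizontal marks with error bars give the mean and SD of 100 shifted lists. Coverage rose from 26.7% within 250 bp to 33.1% between 500 and 1000 bp and dropped below the shifted level beyond 50 kb.

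Genes of red blood cell development had the highest median of the 17 lists. The median window coverage of the erythroid list was 28.7%, against 7.11% for matched random lists (95% range 2.63 to 13.5%; adjusted permutation p = 0.0017, 28 loci). Of its 30 members, 23 lay above the 75th percentile of all genes, 14 above the 90th and 2 below the median. The highest were Zfpm1 (58.3%; 58.0% in replicate 1 and 57.3% in replicate 2), the alpha-globin gene Hba-a1 (53.2%; 47.3% and 49.1%) and Slc4a1, which encodes the band 3 anion exchanger of the red cell membrane (49.3%; 46.2% and 44.4%). The transcription factor genes Klf1 and Tal1 had 34.2% (32.3% and 31.6%) and 36.7% (31.8% and 33.2%), Bcl11a, which encodes a repressor of globin genes, 40.5% (36.8% and 36.3%), and the beta-globin gene Hbb-bs 28.6% (26.7% and 25.6%). Gata1, on chromosome X, had 12.4% (10.6% and 10.3%). The lowest member was Ank1, which encodes ankyrin 1 of the red cell skeleton, at 1.84% (1.36% and 1.80%). The Ank1 gene model runs on chromosome 8 from 22974844 to 23150497, so most of it lay outside the window and was not measured. Globin genes are near-identical copies, so peaks over their own bodies are uncertain. The list stayed past its threshold in every alternative run.

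The strongest peak in the Hba-a1 window, of fold 9.26, lay between genes on chromosome 11 from 32293612 to 32295782, with its summit 10556 bp from the TSS. The Hba-a1 window held 35 replicated peaks and takes in part of Nprl3, whose introns are known to hold enhancers of the alpha-globin genes. Near Klf1, the strongest peak lay in an intron of Syce2 (chromosome 8, 84871271 to 84875196, fold 8.82). Near Tal1 it was intergenic, 40277 bp from the TSS (chromosome 4, 115089833 to 115097380, fold 8.52), and for Bcl11a it lay in the gene's own intron (chromosome 11, 24099642 to 24103780, fold 9.23). Near Hbb-bs it lay over an exon of the non-coding gene Gm15115 (chromosome 7, 103829191 to 103830628, fold 7.37).

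Genes of the hepatocyte lineage did not stand out as a group. The hepatocyte and hepatoblast list had a median window coverage of 10.6%, against 6.24% for random lists (adjusted permutation p = 0.338, 24 loci). Against random lists matched on GC content, chosen after seeing the data, the random median was 10.2% (adjusted permutation p = 0.938). Of its 26 members, 8 lay above the 75th percentile of all genes, 0 above the 90th and 12 below the median. Genes of plasma proteins were spread widely. Alb, the albumin gene, had 2.22% (3.14% in replicate 1 and 2.24% in replicate 2), at the 34.5th percentile, and Afp, the alpha-fetoprotein gene, 1.16%. Apob (0.335%), Ttr (1.60%), Serpind1 (1.67%), Rbp4 (3.73%) and Fgb (4.94%) were also low. Apoa2 had 23.5%, Apoa1 20.5%, Vtn 17.4%, Ahsg 16.3% and Trf 14.9%. All of these but Alb and Afp were chosen after their values were seen. The strongest peak in both the Alb and the Afp window, of fold 3.06, was intergenic, on chromosome 5 from 90442163 to 90442610, with its summit at −18616 bp from the TSS of Alb. Hnf4a, a regulator of hepatocyte identity, had 11.0%, and the highest member was Tfr2, a transferrin receptor of hepatocytes that erythroid cells also express, at 27.9%. Adult hepatocyte metabolism genes had 2.51%, against 5.11% (adjusted permutation p = 0.338, 28 loci); 8 of 28 had no coverage, and the highest, Hpd at 43.2%, had its strongest peak in Setd1b. Over gene bodies with 10 kb flanks, the adult list was lower than random lists (0.683% against 7.98%, adjusted permutation p = 0.0178).

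Compared directly, hepatocyte windows were covered less than erythroid ones. The means were 11.5% ± 8.61 (SD, 24 loci) and 29.0% ± 15.9 (SD, 28 loci), a difference of −17.6 percentage points (two-sided permutation test, p = 6e-05). The difference was −16.4 points in the list of replicate 2 alone and −16.1 points in that of replicate 1 alone.

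**Figure D3:**
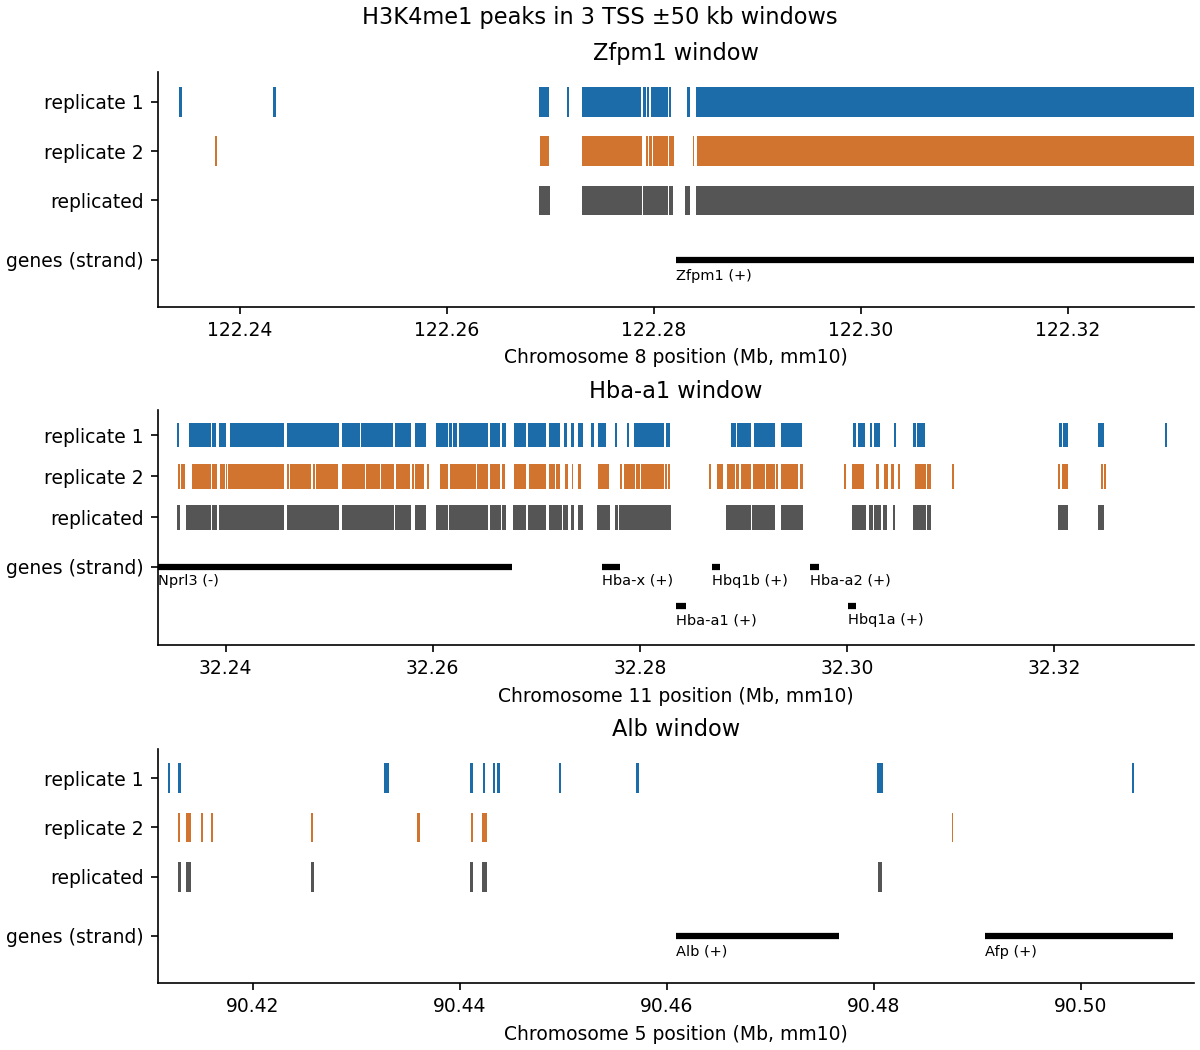
Boxes mark peaks of replicate 1, replicate 2 and the replicated list, and black lines protein-coding genes with their strand, along 3 windows of 50 kb on either side of the TSS of Zfpm1, Hba-a1 and Alb (horizontal axes, mm10 position in Mb). Replicated peaks covered 58.3% of the Zfpm1 window, 53.2% of the Hba-a1 window and 2.22% of the Alb window.

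Other blood lineages gave weaker or mixed results. Megakaryocyte and platelet genes had a median of 17.2%, against 6.31% (adjusted permutation p = 0.0249, 19 loci), with 10 of 20 members above the 75th percentile and 8 below the median. Mpig6b (49.4%; 42.1% in replicate 1 and 42.6% in replicate 2), Gp9 (49.0%; 44.7% and 43.9%) and Gp1ba (35.2%; 31.99% and 30.5%), which encode platelet receptors, were highest, Rab27b (0.650%) was lowest, and the platelet chemokine gene Pf4 had 1.88%. The strongest peak of each of the 3 highest windows lay in another gene: Vwa7 for Mpig6b, Rab43 for Gp9 and the non-coding Gm12319 for Gp1ba. The call was lost without replicate 2 (11.98%, adjusted permutation p = 0.224), among strict peaks (0.0567), in windows of 10 kb (0.165), over gene bodies (0.108), with all members kept (0.141) and with GC matching (0.0913), which was chosen after seeing the data. Blood stem and progenitor genes had 10.04%, against 2.52% (adjusted permutation p = 0.0249, 20 loci), led by Lyl1 (61.7%; 56.1% in replicate 1 and 55.7% in replicate 2), Cbfa2t3 (52.7%; 48.05% and 50.8%) and Runx1 (38.3%; 34.6% and 33.6%), with Kit at 21.9% and Angpt1 lowest at 0.832%. The strongest peak in the Lyl1 window lay in Nfix. That list did not pass against random lists that were unmatched (adjusted permutation p = 0.403) or matched on GC content (0.448). The strongest Runx1 peak lay in its own intron (chromosome 16, 92817289 to 92825267, fold 8.15).

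White blood cell lists did not differ from random lists. Macrophage and myeloid genes had a median of 6.76%, against 6.26% (adjusted permutation p = 0.976), with 7 of 24 members above the 75th percentile. They included Spi1, which encodes the myeloid regulator PU.1, at 30.3%, and the neutrophil elastase gene Elane, the highest at 43.9%, with the strongest peak of its window in R3hdm4. B lymphoid genes had 3.66% (adjusted permutation p = 0.474), with Cd79a highest at 28.5% and the B cell regulator Pax5 at 3.03%. T lymphoid genes had 4.71% (adjusted permutation p = 0.980), with Lck highest at 28.1%.

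Lists of the other cell types of the liver were low and within the range of random lists matched on gene density. With GC matching, chosen after seeing the data, 2 of them passed as lower. These were endothelial genes (random range 4.03 to 15.2%, adjusted permutation p = 0.0499) and cholangiocyte genes (3.18 to 15.2%, 0.0204). Stellate and mesenchymal genes did not (0.234). Endothelial genes had a median of 3.15% (adjusted permutation p = 0.668); 4 of 22 lay above the 90th percentile, led by Eng at 40.04%, and Pecam1 had 17.2% (16.98% in replicate 1 and 12.3% in replicate 2). Stellate and mesenchymal genes had 2.00% (adjusted permutation p = 0.668), with 0 of 22 above the 75th percentile, Ecm1 highest at 12.6% and Lhx2 at 4.06%. Cholangiocyte genes had 1.63% (adjusted permutation p = 0.474), with the water channel gene Aqp1, which red cells also express, highest at 56.0%.

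Ubiquitously expressed genes were marked more, and genes of skin and smell less, than matched random genes. The ubiquitous list had a median of 19.9%, against 8.02% (adjusted permutation p = 0.0068, 24 loci), with 15 of 24 members above the 75th percentile; Eef2 (44.9%; 40.4% in replicate 1 and 40.9% in replicate 2), Rplp0 (41.6%; 39.5% and 34.1%) and Actb (36.1%; 33.2% and 30.7%) were highest and the X-linked Pgk1 lowest at 2.83%. The strongest peaks of the Eef2 and Rplp0 windows lay in Zbtb7a and Pxn. Epidermis genes had a median of 0%, against 7.01% (adjusted permutation p = 0.0195, 18 loci), and 12 of 20 members had no coverage, Krt5 and Trp63 among them. Their highest members were Sfn (27.9%; 26.4% in replicate 1 and 22.7% in replicate 2), Tgm1 (25.7%; 23.1% and 20.7%) and Evpl (20.5%; 20.3% and 16.05%), each with the strongest peak of its window in another gene (Zdhhc18, Tinf2 and Srp68). Of the 1134 olfactory receptor genes, 984 had no coverage, and the median of 267 loci was 0%, against 8.95% (adjusted permutation p = 0.0017). Among the 267 loci, the highest were Olfr750 (19.4%), Olfr221 (15.3%) and Olfr370 (14.5%), and Olfr995 was among those at 0%. Of all 1134 receptor genes, 6 lay above the 75th percentile of all genes and 1 above the 90th. Against random lists matched on GC content, a matching chosen after seeing the data, the random median was also 0% for olfactory receptors (adjusted permutation p = 1). Coverage cannot lie below 0%, so that matching could not show the receptors as lower. Epidermis genes did not pass in windows of 10 kb (adjusted permutation p = 0.165) or over gene bodies (adjusted permutation p = 0.0793).

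The lists of other organs lay within the range of random lists matched on gene density. With GC matching, chosen after seeing the data, gut, pancreas and lung genes passed as lower (random range 3.08 to 13.7%, adjusted permutation p = 0.0499). Muscle genes then lay at 0.444 of the random median without passing (0.104), and neuron genes did not pass (0.234). Neuron genes had a median of 1.09% (adjusted permutation p = 0.166), with Neurod1 at 1.07% and Slc17a7 highest at 30.5%. Skeletal and cardiac muscle genes had 4.88% (adjusted permutation p = 0.980), with Myod1 at 0.624% and Ckm highest at 16.4%. Gut, pancreas and lung genes had 2.28% (adjusted permutation p = 0.512), with Pdx1 at 3.11% and Vil1 highest at 31.9%.

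**Figure D4:**
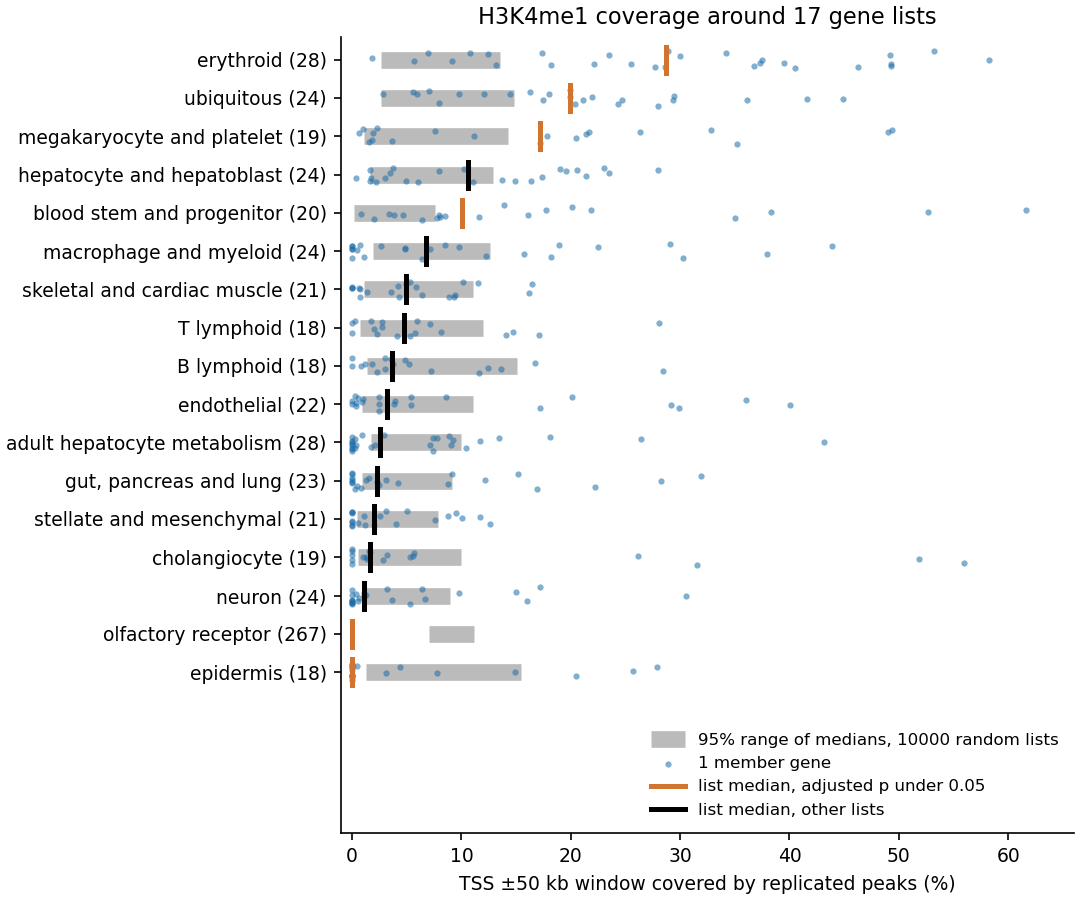
Each point is the window coverage (horizontal axis, %) of 1 gene of the list named on the vertical axis, with the number of loci tested in brackets; vertical bars are list medians, orange where the adjusted p was under 0.05, and grey bands the 95% range of medians of 10000 matched random lists. Single olfactory receptor genes are not drawn. The erythroid median of 28.7% lay above its band (2.63 to 13.5%), and the hepatocyte median of 10.6% lay inside its band (1.63 to 12.9%).

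Long domains of H3K4me1 were also rich in erythroid genes. Stitching gave 18960 domains, of which the top 500, with a median length of 109 kb, held 26.5% of all covered bases and were assigned 1965 genes. Erythroid genes took 14 of 28 places, against 2.53 expected (odds ratio 10.1, Fisher's exact test, adjusted p = 2.4e-07), among them Gfi1b, Lmo2, Nfe2, Tfrc and Fech. Megakaryocyte and blood stem genes had 5 each (Fisher's exact test, adjusted p = 0.125 for both), hepatocyte genes 2 of 24, against 2.17 expected (adjusted p = 1), and olfactory receptors 0 of 267, against 24.1 expected (adjusted p = 3e-10). Gfi1b, Lmo2, Nfe2, Tfrc and Fech were chosen after their values were seen. Unlike the test of window coverage, the domain test matched genes on neither gene density nor GC content. With GC matching, the random median of window coverage for olfactory receptors was itself 0%. Coverage cannot be lower than that, so the matching could not test whether they were low beyond their GC content.

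The largest domain covered chromosome 8 from 120261770 to 120634899, where peaks filled 55.8% of 373130 bp over the gene body of Gse1 and the TSS of Gins2. The others were chromosome 10 from 79840491 to 80191279, a gene-dense region with Stk11, Gpx4 and Elane; chromosome 6 from 38736453 to 38993080, over Hipk2 and Tbxas1; chromosome 11 from 98703166 to 98983123, with the nuclear receptor genes Rara, Thra and Nr1d1; and chromosome 8 from 84770828 to 85085996, which held Klf1, Nfix, Calr and Prdx2. The highest window coverage of any gene was that of Hipk2, a nuclear protein kinase, at 80.8% (76.6% in replicate 1 and 72.7% in replicate 2). Stk11, which encodes the kinase LKB1, followed at 78.2% (74.1% and 71.1%), then Gm48552 (69.7%), Nol4l (68.5%), Gm20708 (66.3%), Ifrd2 (66.2%), Klf13 (66.1%), Klf16 (63.9%), Isyna1 (63.4%) and Hectd4 (63.3%).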

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

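In this part, the tests of GC content and of neighbouring genes for the erythroid pattern, of copy number for chromosome X and of fragment length for replicate 1 were chosen only after the result was seen.

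Peaks outside the comparisons were of 2 kinds, listed because any such peak would be. The replicated list had 5 peaks on unplaced or unlocalised scaffolds, with a fold of at most 2.70; they were not tested. The pooled list held 100625 peaks that are not in the replicated list; they were short (median 225 bp) and weak (median −log10 q of 2.81, against 7.69 for replicated peaks) and covered 25.6 Mb.

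Erythroid windows were covered more than hepatocyte windows, by 17.6 percentage points in the mean. GC content does not explain this as a whole. Against random lists matched on GC content, the erythroid median was still 3.76-fold higher, and 28.7% lay above their 95% range of 3.55 to 13.02%. The GC-matched random medians ran the other way, at 7.65% for the erythroid and 10.2% for the hepatocyte list, though their ranges overlapped. Neighbouring genes in the wide windows do not explain it either, since the difference, hepatocyte minus erythroid, was −31.8 percentage points in windows of 10 kb on either side of the TSS. A candidate explanation, as a hypothesis, is that erythroid cells gave more of the chromatin than hepatocytes did. The prediction written for it, on GATA motifs, was not met. GATA matches were not enriched in peaks over flanks (ratio 0.997, 95% counting interval 0.974 to 1.02). The ratio lay below that of the highest permuted motif (1.006), but by less than its interval. GATA over its permuted motifs was 1.18, against 1.80 for HNF4. That rank turned by the excess of matches, a scale chosen afterwards that favours frequent motifs such as GATA, so the turn does not offset the unmet prediction. Motifs of such different frequency do not settle the share of cells, which stays open. The series has no second group that varies the mix of cells, so the mix itself was not tested.

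Chromosome X was covered less than each autosome: replicated peaks took 0.528% of its sequenced bases, against 2.85 to 7.72% on the autosomes, and the median window coverage of its 948 genes was 0%. Low GC content and gene density may account for part, since mean coverage was 0.172 of that of all autosomal genes and 0.346 of that of autosomal genes matched on both, but X genes (1.90%) stayed below the matched range (5.07 to 5.94%). Matching on repeat content and GC gave 0.379, again below the range (4.59 to 5.46%), so neither is the whole cause. Fewer copies of X in pools of male and female embryos stay open. The prediction for a lower copy number, written after the result was seen, was a similar drop in the fold of X peaks at each quantile. The fold of X peaks was 0.974 of that of autosomal peaks at the median, 0.795 at the 90th percentile and 0.682 at the 99th. The drop was thus not similar across quantiles, and the prediction was not met as written. A difference in gene content could also lower the fold. The fold is a ratio over a control that was not analysed here. A lower copy number of X in that control would cancel in the ratio, so the fold cannot decide this. X inactivation in the female embryos is another open explanation that these lists cannot test.

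Replicate 1 covered 1.07 times as many bases as replicate 2 with fewer peaks. The shortest peaks were 185 bp in replicate 1 and 155 bp in replicate 2, as a longer fragment setting for replicate 1 would give. In 103188 pairs, replicate 1 peaks were longer by a median of 44 bp, and taking the 30 bp difference of the shortest peaks off each replicate 1 peak brought the ratio to 1.02. Replicate 1 still covered more bases, so peak extension of this size is not the whole cause. What accounts for the rest is open; a difference in depth is among the explanations left, and depth is unknown. No biological explanation was tested.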

How the results depend on the processing

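Strict peaks of 1 replicate against the other's whole list, and random lists matched on GC content, were chosen after seeing the data. Of 153 alternatives set beforehand for the comparisons, 129 kept the direction and the side of the threshold (or, with no test, roughly the value) and 8 changed direction; of 19 added ones, 9 did and 2 changed direction. Of 114 for single distance bins, features and domain lists, 107 did and 7 changed direction. Every change of direction was in a list that was not past its threshold in either setting. Every alternative planned was run. Erythroid genes passed in every alternative of the window coverage and domain tests. Ubiquitous genes passed in every one of window coverage, but in long domains they passed in no setting (Fisher's exact test, adjusted p = 0.654 in the main run). The hepatocyte against erythroid difference ran from −31.8 to −16.1 points. Strict peaks of replicate 1 were found in the whole list of replicate 2 in 88.2% of cases, and the reverse in 89.3%; at −log10 q of at least 5 the replicate lists held 56027 and 62711 peaks.

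Spearman's rho of the fold was 0.648 among strict peaks and 0.694 for −log10 p. The share of replicated peaks covered by replicate 1 was 93.2% at 1 bp and 53.3% at 80%, and by replicate 2, 93.6% and 45.0%, as the looser and tighter rules imply. Megakaryocyte genes missed the threshold among strict peaks (14.2%, adjusted permutation p = 0.0567), in windows of 10 kb (19.8%, 0.165), over gene bodies (15.7%, 0.108), with all members kept (14.2%, 0.141) and with GC matching (17.2%, 0.0913); with 1 replicate's list alone they ran from 11.98% to 15.6%, and the call was lost without replicate 2. Blood stem genes missed it without matching (10.04%, 0.403) and with GC matching (10.04%, 0.448). Epidermis genes missed it in windows of 10 kb (0%, 0.165) and over gene bodies (0%, 0.0793). Muscle genes, close to random lists to begin with, fell below them among strict peaks (3.597%), in windows of 10 kb (0%), over gene bodies (2.07%), without matching or with GC matching (4.88% each) and with 1 replicate's list alone (3.93% to 4.15%). Macrophage genes did in windows of 10 kb (7.60%), with GC matching (6.76%) and without replicate 2 (5.24% to 5.35% with 1 list alone). The numbers in long domains crossed the expected number for endothelial (0) and ubiquitous genes (1) with 5 kb stitching, for macrophage genes with 1000 domains (5) and with 1 list alone (3 to 4), for hepatocyte genes without replicate 2 (1 to 3 with 1 list alone) and for ubiquitous genes without replicate 1 (2 to 6). The relative difference of megakaryocyte genes between replicates was −1.27 points among strict peaks. Adult hepatocyte genes passed, as lower, over gene bodies (0.683%, 0.0178). With GC matching, endothelial (3.15%, 0.0499), cholangiocyte (1.63%, 0.0204) and gut, pancreas and lung genes (2.28%, 0.0499) passed as lower. Olfactory receptors no longer did (0%, 1), but their random median was also 0%, so they could not pass as lower. Other than the random medians, which moved with the matching, the cause was not tested. Of 219 alternatives for named genes, 157 moved the coverage by more than 1 SD of the replicates, and over all named genes the median change was −1.98 points among strict peaks, −3.55 without replicate 1 and −2.61 without replicate 2. Depth is unknown and limits how many weak peaks each list could hold.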

Other observations

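The gene families in this part, and the tests on them, were chosen only after the results on the 17 lists were seen; the motif test was fixed before its result was seen, and the comparison by excess of matches was added after it.

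Genes of haem synthesis and of iron uptake were marked more than random genes, with medians not far above that of the ubiquitous list (19.9%). Haem synthesis genes had a median window coverage of 25.8%, against 10.9% for random lists matched on gene density (adjusted permutation p over 18 families = 0.0369, 10 loci, 4 of them also in the erythroid list), with Fech, Ppox and Abcb10 highest. Iron uptake and storage genes had 21.6%, against 5.03% (adjusted permutation p = 0.0081, 10 loci, 2 also in the erythroid list), led by the ferritin genes Fth1 and Ftl1. Autophagy and mitophagy genes, a process by which maturing red cells clear their organelles, had 22.3%, against 5.88% (adjusted permutation p = 0.0090, 12 loci), led by Foxo3 and Ulk1. Ribosomal protein genes had 19.5%, against 9.15% (adjusted permutation p = 0.0012, 76 loci), and ubiquitin-conjugating enzymes, among them Ube2o, which remodels the proteome of reticulocytes, 14.4%, against 6.28% (adjusted permutation p = 0.0086, 36 loci). These 5 families also passed against random lists matched on GC content. No test separated a link to red cells from general expression.

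Cytochrome P450 genes were low, and complement and coagulation genes unremarkable. The P450 family was taken by gene name and not by expression in the liver. Cytochrome P450 genes had 0.341%, against 3.86% (adjusted permutation p = 0.0012, 65 loci, 6 also in a hepatocyte list), and 32 of the 65 had no coverage. Complement and coagulation genes had 4.26%, against 5.40% (adjusted permutation p = 0.733, 17 loci). Keratin genes had 0.421%, against 10.4% (adjusted permutation p = 0.049995, 11 loci), and vomeronasal receptors 0%, against 3.93% (adjusted permutation p = 0.0012, 162 loci). GC matching brought the random median of the latter to 0%, so it could not show them as lower. MAP kinases and their regulators had 11.7%, against 5.35% (adjusted permutation p = 0.0278), which was lost with GC matching (adjusted permutation p = 0.290), and Hox genes 1.66%, against 10.7% (adjusted permutation p = 0.176), lower only with GC matching (adjusted permutation p = 0.0154). With GC matching, Sox genes also passed as lower (adjusted permutation p = 0.0486) and histone genes as higher (adjusted permutation p = 0.0027). KLF genes (9.54%, adjusted permutation p = 0.105), histone genes (26.2%, 0.326), STAT genes (18.2%, 0.168), cyclins (11.1%, 0.124), ABC transporters (5.70%, 0.559), Sox genes (3.11%, 0.733) and protocadherins (0%, 0.0864) did not pass with matching on gene density.

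The hypothesis that erythroid cells gave a larger share of the chromatin than hepatocytes predicted that GATA motifs would be enriched at replicated peak centres beyond all permuted motifs and more than HNF4 and HNF1 motifs. The prediction was not met. In 15000 peak centres of 500 bp against flanks 3 kb away outside all pooled peaks, the GATA motif had a ratio of 0.997 (95% counting interval 0.974 to 1.02), below the highest of its 40 permuted motifs (1.006). It exceeded their median by a factor of 1.18 (permutation p = 0.0488, adjusted over the motifs 0.0854), HNF4 by 1.80 and HNF1 by 3.33. The HNF1 value rests on 20 matches in peaks and 10 in flanks. Its ratio of 1.999 only equalled that of its highest permuted motif, and its counting interval (0.936 to 4.27) includes 1. By the bound set beforehand, the GATA result would count against the hypothesis, both below its highest permuted motif and below HNF4 and HNF1. The rank of the motifs was by a ratio, although their matches in flanks differ widely (1.98 per kb for GATA, 0.0109 for HNF4 and 0.00133 for HNF1). By the excess of matches over the permuted level, a comparison chosen after the ratios were seen, the rank turned: 0.304 per kb for GATA, 0.00804 for HNF4 and 0.00187 for HNF1. GATA matches are far more frequent than those of HNF4 and HNF1, so almost any gain over its permuted motifs would rank GATA first by excess. That rank therefore does not offset the prediction, which stays unmet. GATA lay below its highest permuted motif by less than its interval, and the motifs compared differ widely in frequency. The test thus does not settle the share of cells.

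The motifs of ETS factors (ratio 1.36), HNF4 (1.66), FOXA (1.11), CEBP (2.11, from 9 flank matches) and the muscle factor MEF2 (1.10) each exceeded all of their permuted motifs. So did the NFE2 motif (1.27), which AP-1 factors share, so it does not single out NFE2. The permutation p was 0.0244 for each, the smallest that 40 permuted motifs allow. The counting intervals of CEBP (0.955 to 4.66) and MEF2 (0.839 to 1.44) include 1, and HNF4 barely exceeded its highest permuted motif. With adjustment over the motifs, none passed the threshold (0.0569 each). The smallest p allowed limits what can pass after adjustment, so this miss says little about the motifs. The KLF motif had only 27 permuted motifs and the RUNX motif 34. The GATA, HNF1, KLF, TAL1, RUNX, POU, SOX and REST motifs did not exceed all of theirs.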
